A study of Homo sapiens with 2 samples.

How the data were processed

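RNA of H358 cells, an established line of non-small cell lung cancer, was sequenced as full-length cDNA in 1 library from vehicle (DMSO) cells and 1 library from cells given cisplatin at 100 µM; the column headers of the cisplatin library carry 24 h. Per the labels' protocols, 1 µg of RNA was reverse transcribed with a SMARTer kit, the cDNA was amplified by 14 PCR cycles, purified in fractions at bead ratios of 0.4x and 1x that were pooled in equal molarity, and each library was run on 4 SMRT cells of a Sequel I instrument with 10 h movies. Per the submitters' processing notes, minimap2 2.17-r941 and the human build hg19 were used.

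The deposited tables list single circular consensus reads with their hg19 positions, per the file headers. A table of intronic polyadenylation (IPA) reads pairs each read with a region of the gene lying before the last exon, and in every deposited entry the 3′ end of the read lies inside that region (0 exceptions). A table of last exon (LE) reads pairs each read with the last exon of a gene. The deposited lengths are genomic spans in bases, end minus start, with 0 exceptions in either library, so they include introns and are not transcript lengths. A whole-number score per region is also deposited; the file headers do not say what it means and it was not used. How reads were assigned to genes beyond these columns is not given in the sources used here. All columns that carry sample values were used.

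Each read was counted once. A read paired with several regions was given to 1 of them, by mapping quality, then by the nearest last exon end for LE reads or a region holding the read's start for IPA reads. A read present in both tables (47078 in DMSO and 41171 in cisplatin) was counted as LE. This gave 998781 reads in DMSO (174508 IPA and 1196276 LE entries before counting reads once) and 798375 in cisplatin (170514 and 946409 entries). Sites are groups of 3′ ends of 1 gene lying within 50 bases of each other.

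The IPA share is the percentage of IPA reads among IPA plus LE reads, with exact Clopper-Pearson intervals of 95%. Shares were compared with 2-sided Fisher exact tests per gene, in genes with at least 10 reads in each library and at least 10 IPA reads over both, with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression is the log2 ratio, cisplatin over DMSO, of reads divided by all assigned reads of the library, with a prior of 0.5 reads, in genes with at least 20 reads over both libraries. A gene was called at an adjusted p under 0.05 in a Fisher exact test and a ratio of at least 2-fold; the standard error given beside a log2 value covers counting only. A fold against 0 reads is a lower bound computed with 3 counts in the empty library, and a share of 0 is given with the upper limit that 3 counts set in place of an interval. Spans are medians with 95% intervals from order statistics of the reads, and within genes they were compared in genes with at least 20 reads in each library. The position of IPA could not be sorted into 5′ untranslated regions and first introns, because no hg19 annotation was used here; the first 10% of the gene region, counted from its annotated start, was used in its place. Transcript lengths came from GENCODE transcripts of GRCh38 matched by gene name only (8791 of 9286 genes, 94.7%), with no coordinate moved between builds.

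The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Named are the 10 largest rises and the 10 largest falls of IPA share and of expression among the genes past the threshold, up to 4 called members of each gene list by read number, PRKAR1B, PHF20, PCF11 and CSTF3 in any case, and the 5 genes with the most IPA reads in each library. The lists were p53 targets, immediate early genes, integrated stress response, heat shock, NRF2 and metallothionein, DNA repair, cleavage and polyadenylation, splicing, transcription elongation, ribosomal proteins, nuclear oxidative phosphorylation, cell cycle, apoptosis, lung epithelial identity, genes with described intronic polyadenylation, and markers of fibroblasts, leukocytes and endothelium. The median of each list is placed among 10000 random lists of the same size matched on reads.

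After the data were seen, a second set of reads was defined. Restricted reads have a mapping quality of at least 30 and a span of at least 350 bases, and their IPA reads start within 100 bases of the gene region or inside it and are not mirrored. A mirrored read is an IPA read for which an LE read of either library is listed on the opposite strand with both ends in the same or an adjoining window of 50 bases, and LE reads are called mirrored by the same rule. Where mirrored reads were left out, this was done for IPA reads only, and mirrored LE reads were kept. The length limit was added in a later step, after a class of IPA reads of 270 to 340 bases had been seen. Restricted reads from the gene start also begin within 1000 bases of the annotated start of their gene, in both classes. The naming rule was applied again to both sets. Other alternatives planned or added were another scaling, other read minimums, all entries counted, thinning to equal depth and matching of read lengths. A beta-binomial test with an assumed overdispersion of 0.05 and a negative binomial test with an assumed dispersion of 0.04 were also run.

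With 1 library per treatment, a test on reads compares these libraries and not the treatments. The reads carry no molecular identifiers after PCR, so intervals and bounds cover counting error only. The tests were first tested on simulated data, drawn with counting error only around a profile common to both libraries. The calls of unchanged genes there do not cover variation between libraries or PCR duplicates. For expression (9253 genes), 66 of 100 changes of 2.5-fold and 76 of 100 changes of 4-fold were recovered, and 5 of 9067 unchanged genes were called. For IPA share (2463 genes), 15 of 100 changes of 10 percentage points and 49 of 100 changes of 30 points were recovered, and 1 of 2267 unchanged genes was called. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.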

Results

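The data consist of single PacBio reads of polyadenylated RNA from H358 cells, a non-small cell lung cancer line, given cisplatin, a platinum drug that crosslinks DNA, or its vehicle DMSO. The DMSO library held 998781 assigned reads from 4 SMRT cells of 222429 to 273250 reads each, and the cisplatin library 798375 reads from 4 SMRT cells of 188760 to 205002 reads. Of these, 95693 and 98260 were intronic polyadenylation (IPA) reads, which end in a gene before its last exon. The other 903088 and 700115 were last exon (LE) reads. Each treatment had 1 library, so no difference has a replicate check, and every test compares the reads of these libraries. The libraries shared 0 run days, so sequencing run and treatment cannot be told apart.

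The design asked which genes end more of their transcripts at intronic sites after cisplatin. ANAPC1, a subunit of the anaphase-promoting complex, rose from an IPA share of 20% (95% interval 8.44 to 36.9) to 92.9% (76.5 to 99.1; adjusted Fisher exact p = 1.2e-07). PRKAR1B, a regulatory subunit of protein kinase A, rose from 21.2% (13.8 to 30.3, 104 reads) to 86.1% (70.5 to 95.3, 36 reads; adjusted exact p = 2.6e-10). Of its IPA reads 28.3% were 270 to 340 bases long and 37.7% mirrored, and the reads at its main site around 744646 (0 and 15) had a median span of 326 bases; restricted reads left 4 and 14, a share of 4.94% (1.36 to 12.2) and 73.7% (48.8 to 90.9). NOP58, a core protein of box C/D small nucleolar ribonucleoproteins, rose from 22.7% (11.5 to 37.8) to 57.6% (44.8 to 69.7; adjusted exact p = 0.00249). From the gene start, where it also passed a beta-binomial test, which allows for overdispersion between libraries, it had 0 of 25 reads, which allows up to 12%, and 65.0% (48.3 to 79.4). PAPOLA, the canonical poly(A) polymerase, rose from 19.4% (14.1 to 25.6) to 64.2% (52.8 to 74.5; adjusted exact p = 9.6e-11), and POLH, the translesion DNA polymerase eta, from 7.14% (1.5 to 19.5) to 57.9% (33.5 to 79.7; adjusted exact p = 3.9e-04). In the other direction ENSA, an inhibitor of protein phosphatase 2A, fell from 38.2% (33.3 to 43.3) to 6.18% (3.64 to 9.71; adjusted exact p = 4.9e-21). In the beta-binomial test with all reads, ANAPC1 and PRKAR1B kept their call, and NOP58, PAPOLA, POLH and ENSA lost it.

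Mirrored reads, whose ends are shared by an LE read on the other strand, made up 94.3% of the LE reads of PRKAR1B, 53.2% of those of POLH and none of those of ANAPC1, NOP58, PAPOLA and ENSA. In pairs such as RPL35 and WDR38 or KRT18 and KRT8, the opposite strands held about equal reads (51.8% and 52.9% on the strand of the partner in DMSO). Which gene mirrored reads come from is therefore not resolved, which limits every share and ratio given with a high percentage of them.

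With restricted reads from the gene start, their sites lay at different depths within their genes (hg19, 1-based). For ANAPC1 (chromosome 2, 112526984 to 112641741, minus strand), 0 DMSO and 25 cisplatin reads ended around 112638031, 3711 bases from the gene start. For NOP58 (chromosome 2, 203130515 to 203168108, plus strand), 0 and 21 reads ended around 203141078, 10564 bases in. PAPOLA (chromosome 14, 96968713 to 97031291, plus strand) had 7 and 27 reads around 96998066, 29354 bases in. PRKAR1B (chromosome 7, 590240 to 767313, minus strand) had 3 and 9 reads around 756255, 11059 bases in. ENSA (chromosome 1, 150595336 to 150602098, minus strand) had 115 and 5 reads around 150596091, at 88.7% of the region. Whether a site lies in an intron or in an alternative last exon was not resolved.

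Over all assigned reads, the IPA share was 9.58% (9.52 to 9.64) in DMSO and 12.3% (12.2 to 12.4) in cisplatin, a difference of 2.73 percentage points (2.63 to 2.82). Restricted reads gave 5.41% (5.36 to 5.45) and 5.97% (5.91 to 6.03), a difference of 0.565 points (0.491 to 0.638; Fisher exact p = 8.7e-52). From the gene start the shares were 4.03% (3.99 to 4.08) and 4.88% (4.82 to 4.94), a difference of 0.850 points (0.773 to 0.927). IPA reads with a mapping quality under 30 made up 12.7% in DMSO and 23.3% in cisplatin, and mirrored IPA reads 31.4% and 22.1%. In genes with the shortest transcripts, up to 1628 bases, the restricted share was 3.21% in DMSO and 3.00% in cisplatin, while it rose in each of the longer quartiles, by 1.49, 3.59 and 5.61 points.

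**Figure D1:**
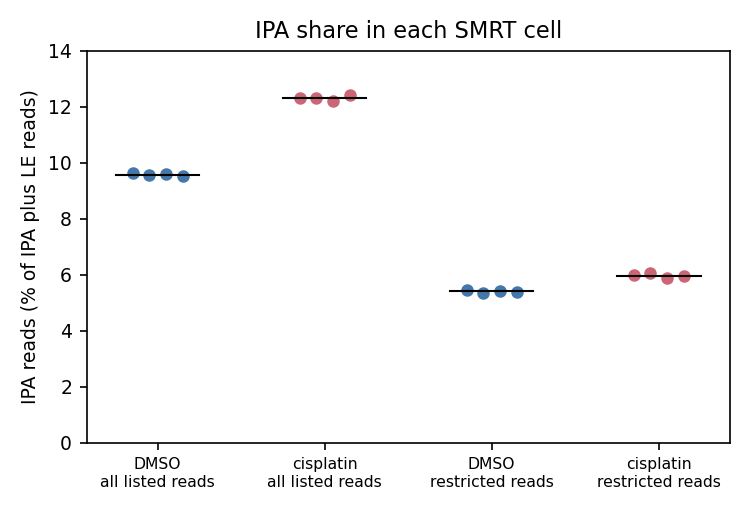
IPA reads as a percentage of IPA plus LE reads in each SMRT cell of the DMSO (blue) and cisplatin (red) libraries, for all assigned reads and for restricted reads; points are SMRT cells and lines are library means. All reads lie at 9.52% to 9.65% in DMSO and 12.2% to 12.4% in cisplatin, and restricted reads at 5.35% to 5.47% and 5.89% to 6.05%.

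Per gene, the IPA share changed in 718 of 2443 genes tested with all reads, 680 higher and 38 lower in cisplatin. With restricted reads it changed in 274 of 1384 genes (261 higher, 13 lower), and with restricted reads from the gene start in 119 of 606 (113 higher, 6 lower). With read lengths of the libraries matched, 220 genes were called with all reads (177 higher) and 80 with restricted reads (67 higher, 13 lower). All reads and restricted reads called 263 genes in common, 262 of them in the same direction. The beta-binomial test called 112 genes with all reads, 111 higher and MAPKAPK5-AS1 lower, the latter with 84.8% of its IPA reads mirrored. With restricted reads it called 4, ZC3H3, ANAPC1, PRKAR1B and DNAJC5, the last chosen after its values were seen. All of these but ZC3H3 lay just under the threshold. From the gene start it called 3, ANAPC1, NOP58 and PRKAR1B.

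The 10 largest rises with all reads were in SNHG3, DYM, ZC3H3, INTS2, SLC25A12, LAMC1, FAM105A, MB21D2, FOXK2 and AHDC1, and each kept its call in the beta-binomial test. With restricted reads from the gene start, none of these 10 genes had enough reads for a test. Their cisplatin IPA reads there numbered from 0 to 3 per gene, so these rises were not seen in such reads. In 7 of these 10 genes most IPA reads were 270 to 340 bases long. SNHG3, a small nucleolar RNA host gene, is 1 of them; it went from 0 IPA and 10 LE reads to 78 IPA and 5 LE reads, with 91.0% of the IPA reads in that length class. ZC3H3, a zinc finger protein of mRNA export, rose with restricted reads from 8 IPA and 113 LE reads (6.61%, 2.90 to 12.6) to 172 IPA and 4 LE reads (97.7%, 94.3 to 99.4; adjusted exact p = 3.4e-63). Its site around 144536244 on chromosome 8 (gene region 144520258 to 144623620) took 1 and 122 of these IPA reads, with a median span of 632 bases. From the gene start ZC3H3 had 1 IPA and 99 LE reads in DMSO, and 0 IPA and 2 LE reads in cisplatin. The 10 largest falls were in MAPKAPK5-AS1, LAMP2, TCEA2, RPL23AP82, CCDC142, MPC2, ZGPAT, TST, TDRKH and ENSA. In 6 of these, MAPKAPK5-AS1 (84.8%) among them, most IPA reads were mirrored. All but MAPKAPK5-AS1 lost their call in the beta-binomial test, and from the gene start MAPKAPK5-AS1 had 0 IPA reads in either library. LAMP2, a lysosomal membrane protein with alternative last exons, had no mirrored IPA read and fell from 57.0% (46.3 to 67.2) to 10.0% (2.11 to 26.5; adjusted exact p = 5.7e-05).

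Restricted reads placed ZC3H3, TMCO3, LRP11, ANAPC1, ITFG1, PRKAR1B, PPTC7, RAI1, C2CD3 and MAD1L1 among the largest rises, and LAMP2, SLC25A51, TCEA2, TDRKH, ENSA, SLC39A3, CHID1, MBD1, FLAD1 and ABCF2 among the largest falls. From the gene start the largest rises also took in CHAMP1, CCDC144NL-AS1, EXTL3, KIFC3, DDX5 and PTGR2, and the 6 falls were LAMP2, SLC39A3, ENSA, TDRKH, FLAD1 and ABCF2. Each of these rises was also called with all reads except that of DDX5, which stood at 26.5% and 35.7% there; its LE reads numbered 25 and 27 with all reads, and 17 and 2 from the gene start. SLC39A3, a zinc transporter, went from 33.3% (19.6 to 49.5) to 0 of 30 reads, which allows up to 10.0% (adjusted exact p = 0.00257), from the gene start, and lost its call in the beta-binomial test. Over the 261 genes that rose with restricted reads, IPA reads relative to library size were 1.64 times as many in cisplatin and LE reads 2.14-fold fewer, and 216 of these genes had both. These genes were selected on the same reads, so the 2 directions are not a separate result. Over all genes measured with restricted reads, the median log2 ratio of expression was −0.47.

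**Figure D2:**
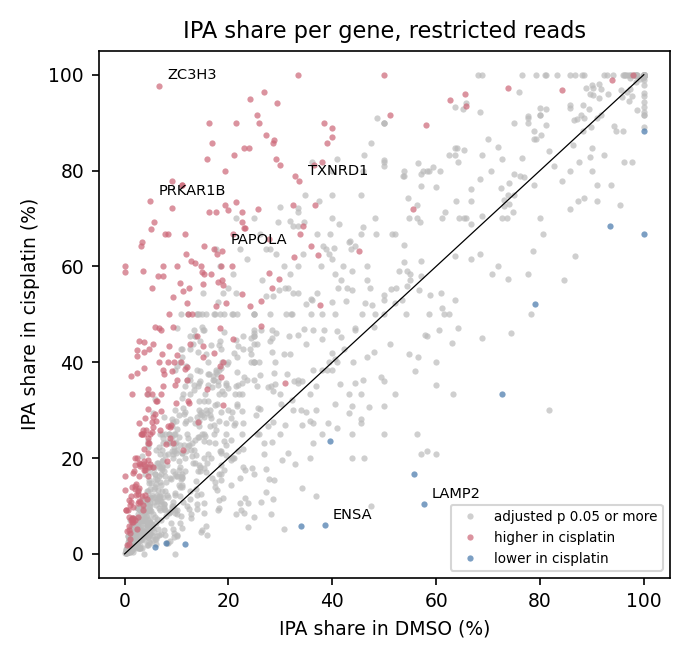
IPA share of each of 1384 genes tested with restricted reads in DMSO (horizontal, %) and cisplatin (vertical, %), with the line of equal shares. Genes past the threshold are red (261 higher in cisplatin) or blue (13 lower), and ZC3H3, PRKAR1B, TXNRD1 and PAPOLA stand above the line while ENSA and LAMP2 stand under it.

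Of the 4 genes named in any case, PRKAR1B also rose from the gene start, from 3.95% (0.822 to 11.1) to 72.2% (46.5 to 90.3). CSTF3, the CstF-77 subunit of the cleavage stimulation factor, rose with all reads from 5.45% (1.14 to 15.1) to 42.9% (24.5 to 62.8; adjusted exact p = 6.2e-04), lost its call in the beta-binomial test, and had too few restricted IPA reads for a test (2 and 7). PCF11, a cleavage and polyadenylation factor, stood at 12 of 24 reads (29.1% to 70.9%) and 82.8% (64.2 to 94.2), short of the threshold (adjusted exact p = 0.0577). Its site around 82869921 on chromosome 11, 1785 bases from the gene start, held 3 and 19 reads. PHF20, a chromatin reader protein, stood at 77.8% (62.9 to 88.8) and 92.6% (75.7 to 99.1), also short of the threshold (adjusted exact p = 0.354).

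Among the gene lists tested with all reads, 3 lay outside the central range of random lists. With restricted reads from the gene start 0 did, and heat shock had too few tested genes there for a median (4). Heat shock genes had a median change of 3.63 points over 6 genes (percentile 97.9), with the chaperones HSP90AA1, HSP90AB1 and HSPD1 higher and 0 lower. HSP90AA1 rose from 19.4% (17.2 to 21.9) to 31.4% (28.3 to 34.6; adjusted exact p = 4.4e-08), a call lost in the beta-binomial test, as were those of HSP90AB1 and HSPD1. Ribosomal proteins had a median of 0.0646 points over 30 genes (percentile 1.13), with RPL31 higher and 0 lower; the median turned to −0.0391 points with restricted reads, and RPL31 lost its call in the beta-binomial test. Lung epithelial identity had a median of −0.380 points over 5 genes (percentile 2.16) with KRT8, a keratin, lower; adjusted over the list alone, 1 gene was higher and 1 lower. KRT8 fell from 59.2% to 46.3% with 97.4% of its IPA reads mirrored, and with restricted reads it rose from 0.800% to 2.05%; both calls were lost in the beta-binomial test.

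Over all 2443 genes tested with all reads, the median change of IPA share was 8.33 points, with 680 genes higher and 38 lower. A list with more genes higher than lower therefore does not stand apart by that alone. Cleavage and polyadenylation genes had a median change of 14.6 points over 12 genes (percentile 91.0), with CSTF3, PAPOLA and SSU72 higher and 0 lower; all 3 calls, like those of the other lists here except for PRKAR1B, were lost in the beta-binomial test. Transcription elongation (7 genes, 27.7 points, percentile 91.5) had CCNT1, SUPT16H and SSRP1 higher, and 4 genes adjusted over the list alone. Splicing (18 genes, 3.68 points, percentile 50.9) had SNRPD1, SF3A3, SF3B2, SRSF11 and HNRNPC higher, and 6 genes adjusted over the list alone. Cell cycle genes (12, 1.95 points, percentile 22.5) had CCND1, CCNE2 and AURKB higher, and with restricted reads their median turned to −0.0366 points (percentile 1.94). Oxidative phosphorylation (12 genes, 1.41 points, percentile 45.7) had NDUFS1 and COX4I1 higher and ATP5J lower. Genes with described intronic polyadenylation (10, 15.8 points, percentile 63.7) had PRKAR1B and CSTF3 higher. DNA repair (7 genes, 9.14 points, percentile 40.2) had POLH higher, and apoptosis (6 genes, 1.97 points, percentile 14.1) had 0 called. NRF2 and metallothionein (5 genes, 1.40 points, percentile 86.5) had TXNRD1 higher. TXNRD1, a thioredoxin reductase, rose with restricted reads from 33.7% (30.7 to 36.8) to 77.8% (73.8 to 81.4; adjusted exact p = 3.5e-55), a call lost in the beta-binomial test, and none of its restricted reads began at the annotated gene start.

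Where not given, the counts in these lists were the same adjusted over the list alone. The p53 targets (2 genes tested, POLH higher), immediate early genes (1), the integrated stress response (2) and the markers of fibroblasts, leukocytes and endothelium (0) had too few tested genes for a median.

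IPA ends also lay nearer to gene starts in cisplatin. EXTL3, a glycosyltransferase of heparan sulfate synthesis, and POLH had 0 DMSO reads at their main sites, 1054 and 1172 bases from the gene start, against 11 and 7 cisplatin reads. The first 10% of the gene region held 23.7% (23.4 to 24.0) of IPA reads in DMSO and 26.0% (25.7 to 26.2) in cisplatin (Fisher exact p = 1.1e-30), and 13.4% and 20.3% of IPA sites. With restricted reads the shares were 5.98% (5.77 to 6.20) and 10.2% (9.91 to 10.5; Fisher exact p = 1.4e-118). The median distance of restricted IPA ends from the gene start was 25762 bases in DMSO and 12670 in cisplatin. These values pool all genes, and positions were not compared within genes. Long genes had fewer reads in cisplatin and LE reads were shorter there too. The change of distance therefore cannot be told apart from another mix of genes or from shorter molecules. The most IPA reads in DMSO fell in KRT8 (2395), LOC101927795 (1417), TSACC (1200), TSPAN9 (1173) and MIR1268A (1155). In cisplatin they fell in RPS29 (1884), TSPAN9 (1849), UBE2Q2P2 (1361), RBFOX2 (1340) and MRPL49 (1327). Of these 9 genes KRT8, LOC101927795, TSACC, MIR1268A and MRPL49 had 92.2% or more of their IPA reads mirrored, and TSPAN9, UBE2Q2P2 and RBFOX2 had 93.6% or more under mapping quality 30, which leaves RPS29, a ribosomal protein.

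For read length the files hold genomic spans, which include introns. LE reads had a median span of 10619 bases (10556 to 10642) in DMSO and 5486 (5467 to 5493) in cisplatin, and IPA reads 5942 (5776 to 5998) and 2236 (2182 to 2299). With restricted reads the IPA medians were 6552 and 4173 and the LE medians 11253 and 6171. Within genes the change was small. Of 5048 genes with at least 20 reads in each library, the median span was shorter in cisplatin in 3901, longer in 815 and equal in 332, and the lower quartile of the log2 ratio over genes was −0.04. The span was at least 2-fold shorter in 519 genes and at least 2-fold longer in 17.

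**Figure D3:**
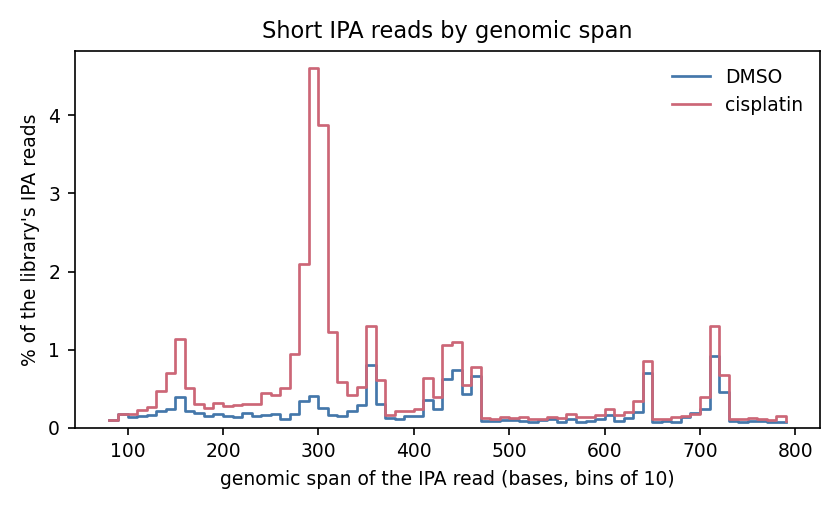
Genomic span of IPA reads under 800 bases (horizontal, bases, in bins of 10) as a percentage of the IPA reads of each library (vertical), DMSO in blue and cisplatin in red. Spans of 270 to 340 bases hold 1.73% of IPA reads in DMSO and 13.8% in cisplatin.

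In expression, FOS, SNAI1, CDKN1A and PMAIP1 were among the genes higher in cisplatin and HSPA5 among those lower. FOS, an immediate early transcription factor, rose from 2 reads to 75 (ratio 46.9, counting interval 12.5 to 394.5; adjusted exact p = 7.9e-23). SNAI1, a transcription factor of epithelial to mesenchymal transition, rose from 3 to 81 (33.8, 11.2 to 167.2). CDKN1A, the p53-induced cell cycle inhibitor p21, rose from 76 to 246 (log2 2.01 ± 0.19, standard error). PMAIP1, the BH3-only protein NOXA, rose from 101 to 522 reads (log2 2.69 ± 0.16; adjusted exact p = 2.5e-89). HSPA5, the chaperone BiP of the endoplasmic reticulum, fell 14.2-fold (11.3 to 18.1) from 1404 to 79 reads (adjusted exact p = 9.8e-251).

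In all, 3575 of 9286 genes changed, 876 higher and 2699 lower (24.5% higher). Scaling by a trimmed mean of log ratios added 0.32 to every log2 value and gave 1478 higher and 1847 lower (44.5% higher). The median of log ratios added 0.30 and gave 1449 and 1891 (43.4% higher). The other largest rises were KLKP1 (2 reads to 307, ratio 192.0, 52.7 to 1593), VTCN1 (0 to 51, at least 21.3-fold), TAT-AS1 (0 to 29, at least 12.1-fold), IDO2 (0 to 22, at least 9.17-fold), LINC00324 and LRRK2 (0 to 20 each, at least 8.34-fold), RSRP1 (2 to 68, 42.5, 11.3 to 358.3) and PLB1 (1 to 38, 47.5, 8.03 to 1926). Of the 10 largest rises 7 had under 20 restricted reads and 5 had no LE read. LRRC4 fell from 199 reads to 3 (53-fold lower, 17.9 to 259.3) with 95% of its LE reads mirrored. Other large falls, in LOC100506388 (77.1% of LE reads mirrored), ZNF362, ZNF865, STAU2-AS1 (79.3%), VAV3, DDX60, ITPK1-AS1 and BMPR1A, went to 0 cisplatin reads from 21 to 35 in DMSO, at least 5.6-fold to 9.33-fold lower. With restricted reads the largest rises also took in VTRNA1-2, ID2 (an inhibitor of DNA binding, 9 reads to 200), CSAG4, RND1, RPPH1, ZNF296 and DLX2, and the largest falls ADAM10 (a membrane metalloprotease, 54 to 0), DIS3L2 and FARP1 (73.9% of LE reads mirrored). PRKAR1B was called lower (log2 −1.19 ± 0.28, 94.3% of LE reads mirrored), while CSTF3 (−0.64 ± 0.33), PHF20 (−0.40 ± 0.35) and PCF11 (0.59 ± 0.39) were not called. With the other scalings the log2 ratios of PRKAR1B, KLF6, ERCC3, HSP90AB1, TNPO1 and DNAJB1 fall short of the 2-fold limit.

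For expression, 5 lists lay outside the central range of random lists, and any list member named beyond the 4 called members with the most reads was chosen after its values were seen. Immediate early genes had a median log2 ratio of 0.88 over 17 genes (percentile 100.0). Of these 6 were higher, among them GADD45B (2.21 ± 0.23), FOS and ATF3 (3.97 ± 0.71), and KLF6 (−1.20 ± 0.41), KLF4 and JUND were lower. The p53 targets had a median of 0.32 over 18 genes (percentile 99.7). CDKN1A, GADD45A (3.01 ± 0.66) and PLK3 (2.12 ± 0.35, 93.0% of LE reads mirrored) were higher, and CCNG1 (−1.71 ± 0.42) and MDM2 (−2.94 ± 0.81) lower. Ribosomal proteins had a median of 0.81 over 72 genes (percentile 99.9), with 0 lower and 18 higher, 45 with either other scaling. RPLP1 (1.21 ± 0.04), RPS19 (1.12 ± 0.04), RPL41 (1.08 ± 0.05) and RPL35 (1.05 ± 0.05, 99.0% of LE reads mirrored) had the most reads.

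Nuclear oxidative phosphorylation genes had a median of 0.70 over 46 genes (percentile 99.8). COX6A1 (1.42 ± 0.06), ATP5I (1.36 ± 0.07), UQCRQ (1.14 ± 0.08) and COX8A (1.18 ± 0.09) stood among 15 higher (25 and 23 with the other scalings), and ATP5A1 and NDUFS1 were lower. Cell cycle genes had a median of −0.76 over 32 genes (percentile 1.53), with CCNE1, a cyclin of the G1 to S transition, higher and 14 lower. These included the replication helicase subunits MCM4 (−1.53 ± 0.15) and MCM5 (−1.42 ± 0.16), the topoisomerase TOP2A (−1.83 ± 0.17) and the mitotic kinase PLK1 (−1.71 ± 0.17, 98.1% of LE reads mirrored). Counts in all lists of expression were the same adjusted over the list alone, except where given.

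The remaining lists lay within the central range of lists matched on reads. Their counts of called genes depended on the scaling. With either other scaling 4 genes of the integrated stress response, 7 of DNA repair and 4 of cleavage and polyadenylation were lower, and 2 of the integrated stress response higher. Splicing then had 8 lower, and transcription elongation 5 lower and 4 higher. In the integrated stress response (16 genes, median −0.85, percentile 8.34, but 0.840 with gene length matched as well) 6 were lower, among them HSPA5, PSAT1 (−1.87 ± 0.25) and TRIB3 (−1.89 ± 0.34), and PPP1R15A (1.61 ± 0.30) was higher. Of heat shock genes (11, −0.39, percentile 7.62) HSPA8 (−1.65 ± 0.06), HSP90AB1 (−1.02 ± 0.07), HSPD1 (−1.37 ± 0.08), DNAJB1 and HSPA4 were lower, 3 genes with the other scalings, and HSPB1 (1.35 ± 0.09) was higher; HSP90AB1 was not called with restricted reads (−0.97). Of DNA repair genes (25, −0.80, percentile 13.7) 10 were lower, among them DDB1 (−1.34 ± 0.19), RPA1 (−2.31 ± 0.32) and ERCC3 (−1.26 ± 0.26), and ERCC1 (1.09 ± 0.21, 86.4% of LE reads mirrored) was higher. Cleavage and polyadenylation genes (23, −0.64, percentile 15.2) had 0 higher and 6 lower, among them PABPC1 (−1.37 ± 0.07), CPSF3 (−1.57 ± 0.29), SYMPK (−1.81 ± 0.34) and CPSF7 (−2.08 ± 0.38), and 7 lower adjusted over the list alone. Genes with described intronic polyadenylation (16, −1.11, percentile 4.62) had 0 higher and 8 lower, 3 with the other scalings, among them TNPO1 (−1.03 ± 0.19), ZFR (−1.88 ± 0.27) and MET (−2.25 ± 0.46); TNPO1 was not called with restricted reads (−0.99).

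Splicing genes (34, percentile 14.6) had a median of −0.25, which turned to 0.07 and 0.05 with the other scalings. SNRPD2 (1.03 ± 0.08) and SNRPB2 were higher, and 4 genes with the other scalings, and 9 were lower, among them HNRNPK (−1.49 ± 0.09), SRSF1 (−2.55 ± 0.18) and SRSF3 (−1.34 ± 0.14). Transcription elongation genes (27, percentile 65.5) had a median of −0.30, which turned to 0.02 with the trimmed mean. SUPT4H1 (1.14 ± 0.19, 83.4% of LE reads mirrored), HEXIM1 and POLR2A were higher, and 6 were lower, among them SSRP1 (−1.37 ± 0.14), TCEA1 (−2.45 ± 0.21, −1.26 with restricted reads) and SUPT16H (−1.75 ± 0.20). Of NRF2 and metallothionein genes (16, median 0.00, percentile 41.6) the ferritin chains FTH1 (1.35 ± 0.03) and FTL (2.07 ± 0.04) and HMOX1 were higher, and TKT (−1.96 ± 0.10) and GCLC (−1.37 ± 0.39) lower. Of apoptosis genes (24, 0.07, percentile 89.2) PMAIP1, CYCS (1.67 ± 0.14), BIK (1.35 ± 0.20), CFLAR and BCL2L11 were higher, and BCL2L1 (−2.06 ± 0.21, 91.1% of LE reads mirrored) lower. Of lung epithelial identity genes (14, −0.42, percentile 13.5) AGR2 (1.10 ± 0.26) and SLPI (3.27 ± 0.65) were higher, and CDH1 (−2.09 ± 0.32), NKX2-1 (−2.21 ± 0.35) and FOXA1 lower. Of the markers of other cell types, leukocytes had 2 measured genes with CD68 higher (21 reads to 39, log2 1.20 ± 0.39), and fibroblasts and endothelium had 0.

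**Figure D4:**
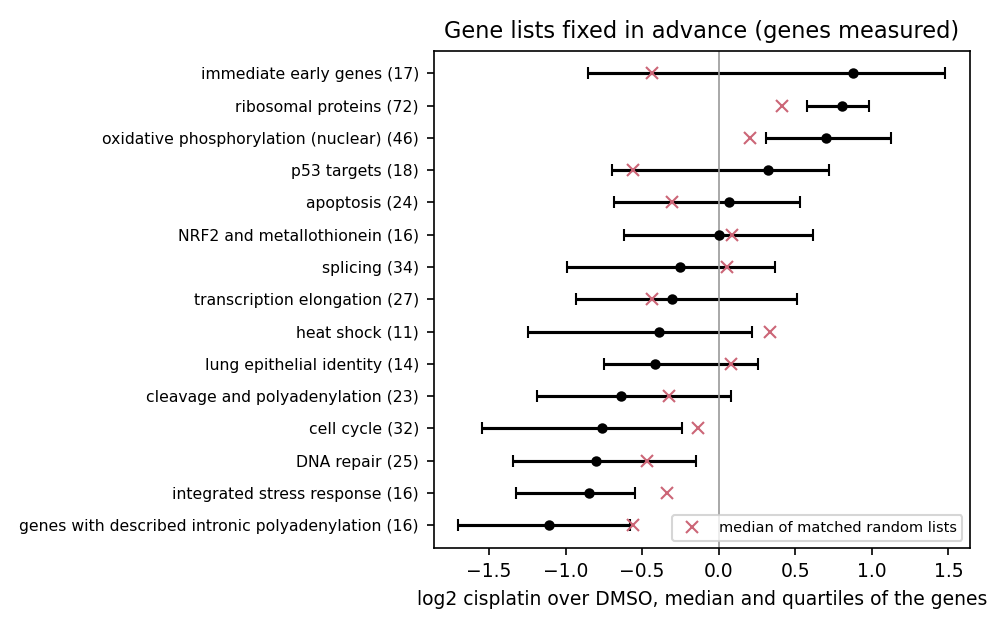
Median log2 ratio of reads relative to library size, cisplatin over DMSO, of each gene list with at least 5 measured genes (points; bars are the quartiles of the genes, and the number of genes stands in parentheses), and the median of random lists matched on reads (crosses). Immediate early genes (0.88), ribosomal proteins (0.81) and oxidative phosphorylation (0.70) stand highest and genes with described intronic polyadenylation (−1.11) lowest; the splicing median changes sign with both other scalings and the elongation median with the trimmed mean.

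Long genes had fewer reads in cisplatin, and VAV3, BMPR1A and MET all lie in the quartile of longest genes. Across 9182 genes, Spearman's rho between the log2 ratio and the genomic length of the gene was −0.42, a relation across genes, which are not replicates. The median log2 ratio was 0.28 in the quartile of shortest genes (up to 9531 bases), then −0.14 and −0.63, and −1.17 in the quartile of longest genes (from 55135 bases). Genes lower in cisplatin made up 13.9% of the shortest quartile and 50.7% of the longest. Ribosomal proteins, with a median length of 4519 bases, and oxidative phosphorylation genes, with 8177, are short, and genes with described intronic polyadenylation, with 94094, are long. The change of IPA share moved the other way, with a median of 1.53 points in the shortest and 15.2 points in the longest quartile of 1370 genes (rho 0.32, restricted reads). LE reads are in the denominator of the IPA share, so a loss of LE reads in long genes raises the share there. The relations of expression and of IPA share with gene length are therefore not separate results.

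**Figure D5:**
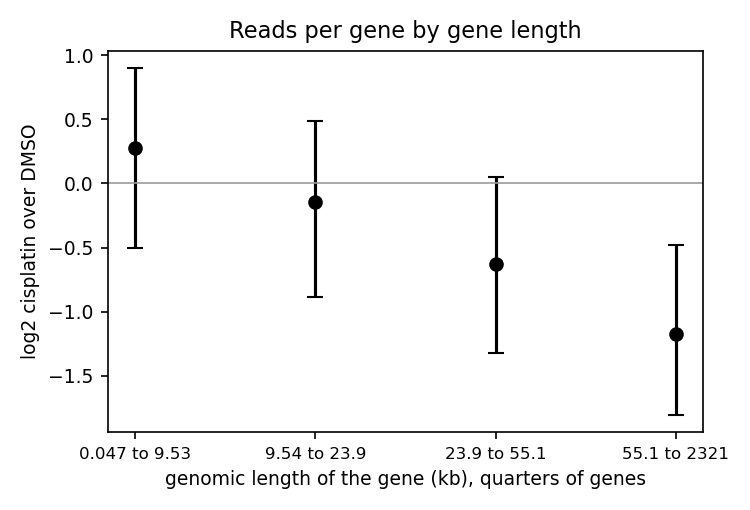
Log2 ratio of reads relative to library size, cisplatin over DMSO (vertical), in quartiles of 9182 genes by genomic length (horizontal, kb); points are medians and bars the quartiles of the genes. The median falls from 0.28 in the shortest to −1.17 in the longest genes.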

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

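All tests in this part were chosen after the result was seen. Signals stood out in features of IPA reads that no planned comparison tested, their mapping quality and a class of short lengths. In cisplatin 23.3% (23.0 to 23.5) of IPA reads had a mapping quality under 30, against a control level of 12.7% (12.5 to 12.9) in DMSO, with SMRT cells at 22.7% to 23.7% and 12% to 13.4%. Spans of 270 to 340 bases made up 13.8% (13.6 to 14.0) of IPA reads in cisplatin (13537 reads), against a control level of 1.73% (1.65 to 1.82) in DMSO (1658 reads). The most frequent span in that range was 302 bases in cisplatin and 281 in DMSO. In cisplatin these reads were assigned to 3027 genes, and AGAP1, a GTPase-activating protein of endosomal traffic, held the most (2 reads in DMSO, 477 in cisplatin), ahead of RBFOX2 (213 and 350) and IL6ST (116 and 220). The 2 signals overlap, as 41.4% of these reads in cisplatin and 53.5% in DMSO had a mapping quality under 30. In cisplatin 7836 of them, in 2232 genes, were at quality 30 or more, not mirrored and started in or near their gene region. The gene of the others is uncertain.

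Of 5 technical explanations for the higher IPA share in cisplatin, the first 3 concern classes of reads. Without reads of uncertain placement the difference was 1.54 points (1.45 to 1.64), and without reads of 270 to 340 bases 1.39 (1.3 to 1.48). Without mirrored IPA reads it was 3.08 points (2.99 to 3.16). Each value argues against the reads left out as the whole cause. Mirrored LE reads stayed in all of these comparisons, so their part in the difference was not tested. Restricted reads, which also drop other reads under 350 bases and IPA reads starting outside their gene region, left 0.565 points. A cisplatin library richer in short molecules would raise the share least in genes with short transcripts, and there the difference was −0.209 points (−0.297 to −0.121), so this explanation stays open for the total. A run batch cannot be told apart from an effect of cisplatin on transcription, because 0 run days hold both libraries. The rise of ANAPC1, none of whose IPA reads fell in these classes, remained after the restriction; priming on genomic A-tracts was not examined here.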

How the results depend on the processing

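Of the alternative values of counts, shares, lengths and relations, 108 kept their direction and size and 44 moved. For the 10 largest rises and 10 largest falls of IPA share and of expression by their call, and for lists by the place of their median among random lists, 508 stayed the same, 24 became weaker, 5 became stronger and 1 reversed; sign changes of list medians and lost calls of single list members are not in these counts. Alternatives that restrict reads by mapping quality, strand, length or gene start, or count reads of both classes as IPA, were chosen after seeing the data. The IPA share was higher in cisplatin under every alternative, by 0.466 points with length-matched reads to 3.17 points with reads of both classes counted as IPA. Genes with a changed IPA share numbered 422 (372 higher) when each site was tested, 220 (177 higher) with length-matched reads and 112 (111 higher, 1 lower) in the beta-binomial test. They numbered 274 (261 higher, 13 lower) with restricted reads and 119 (113 and 6) from the gene start; in the beta-binomial test 4 (4 and 0) and 3 (3 and 0), and with restricted reads matched on length 80 (67 and 13). The lower count was 75 with every entry counted and 15 without mirrored IPA reads, and the higher count 450 without reads of 270 to 340 bases. MPC2 reversed to 3.76 points without mirrored IPA reads.

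The log2 ratio of median IPA span, −1.41, moved to −0.64 with every entry counted, −1.16 with means, −1.14 at mapping quality 30 or more, −1.75 without mirrored reads, −0.98 without reads of 270 to 340 bases, −0.65 with restricted reads, −1.18 from the gene start and −0.97 with reads of both classes counted as IPA. The share of genes with shorter reads, 77.3%, was 73.9% at 50 or more reads, 75.3% with means, 73.3% with LE reads and 74.3% with restricted reads. Genes higher in expression numbered 1478 and 1449 under the other scalings, and at 50 or more reads 2374 changed (1712 lower), as fewer genes were tested. The relation of expression with gene length was −0.53 with LE reads and −0.49 with restricted reads. From the gene start 0 lists of IPA share stood apart. For the other changes the cause was not tested.

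No paired analysis was possible because each treatment has 1 library, and for the same reason no library could be left out. The planned comparison of spans with summed aligned blocks was not run, as spans alone were used here. Depth limits the tests of single genes, since 15 of 100 simulated changes of 10 points in IPA share were recovered.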

Other observations

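The gene families in this part were chosen after the data were seen, whereas the tests of gene length on expression and on gene lists were set before. Of 16 families computed, 6 lay outside the central 95% of random lists matched on reads and gene length. Mitochondrial ribosomal proteins had a median log2 ratio of 0.72 over 77 genes (percentile 100.0 among these lists), with 21 higher, such as MRPL41 (1.36 ± 0.15) and MRPL33 (1.31 ± 0.16), and 1 lower, MRPS27. Proteasome subunits had a median of 0.54 over 42 genes (percentile 99.9), with 9 higher, such as PSMC4 (1.52 ± 0.13), and 2 lower, PSMD1 and PSMD5. Small nucleolar RNA host genes had a median of 1.22 over 14 genes (percentile 100.0), with 8 higher, such as SNHG15 (1.81 ± 0.23), and 0 lower. Aminoacyl-tRNA synthetases had a median of −1.43 over 17 genes (percentile 0.360), with 10 lower, such as AARS (−1.90 ± 0.21) and IARS (−2.07 ± 0.25), and 0 higher. Solute carriers had a median of −0.77 over 141 genes (percentile 0.390), with 49 lower, such as the amino acid transporter SLC7A5 (−1.71 ± 0.10) and the glucose transporter SLC2A1 (−2.32 ± 0.24), and 8 higher. Antisense RNAs had a median of −0.63 over 246 genes (percentile 0), with 86 lower, such as EZR-AS1 (−2.47 ± 0.18), and 22 higher, but EZR-AS1 held 45.1% of the reads of its pair with EZR in DMSO, so their strand of origin is not resolved. Each of these medians kept its sign under the other scalings.

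The lower reads of long genes in cisplatin were weighed against a library richer in short molecules. Within quartiles of transcript length the median rho with genomic length was −0.284, which argues against short molecules as the whole cause. Within quartiles of genomic length the median rho with transcript length was −0.270, so both lengths carry part of the relation. An effect of cisplatin on long genes and a run batch both stay open, since 0 run days hold both libraries.

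The lists that stood apart were weighed against the gene length of their members, among random lists matched on reads and genomic length. The percentiles were 98.5 for ribosomal proteins, 97.7 for oxidative phosphorylation, 98.5 for p53 targets, 99.3 for immediate early genes and 0.350 for cell cycle genes. These values argue against genomic length alone for each of the 5 lists. The random lists were not matched on transcript length, so a library richer in short molecules stays open for these lists. A run batch was not excluded, and no further biological explanation was tested. Genes with described intronic polyadenylation moved to percentile 48.9 among the length-matched lists.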
